A study of Bos taurus with 12 samples.

How the data were processed

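RNA was isolated from groups of 50 bovine cumulus-oocyte complexes and sequenced as paired reads of 150 bases, per the labels' protocols. Trim Galore 0.4.5, STAR 2.5.4b and DESeq2 are named in the submitters' processing notes, without their roles. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here. No coordinates are therefore printed, and reads of overlapping or antisense genes cannot be told apart.

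The deposited count table held raw counts, whole numbers per gene, for 12 libraries and 18057 gene rows. The deposited log2 table held log2 values that differed from log2 of the count by one constant per library, with a count of 0 listed at the value of 0.9 reads. The authors' deposited table of the contrast held a p-value and an adjusted p-value per gene, a log2 fold change, and a signal column per group equal to the mean raw count. It also held 4 columns of other groups, which were not used here. Symbols and gene IDs were taken from the deposited tables. The reference gene table of assembly ARS-UCD2.0 paired none of the Ensembl IDs and was not used for names.

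Of the gene rows, 74 exact copies were dropped, which left 17983, and 2487 of these had a count of 0 in every library. Several rows for one ID occurred for 78 IDs and were kept as deposited. Genes were kept by filterByExpr (minimum count 10, minimum total 15, 6 libraries), which left 12311. Counts were normalised by TMM and tested with edgeR 4.0.16 (glmQLFit, glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM used a prior count of 2. The biological coefficient of variation was 0.146, and the 95% interval of a log2 fold change had a median half-width of 0.217. Intervals are those of the fitted model.

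The 2 groups, the tests, 28 gene lists and the rule for named genes were fixed before the data were examined. The rule took genes that passed the threshold, then the genes of smallest p until 10 were named. It added the most abundant member of each list without a passing member, and 18 genes of oocyte, cumulus and stress function. Not every gene the rule names is reported here. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry (limma 3.58.1), and adjusted over 27 lists. The list of red blood cell markers had too few tested members. Composition was compared with exact two-sided permutation tests over 924 arrangements, adjusted over 12 measures.

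The labels describe the samples as independent replicates. No 2 libraries of a group agreed within counting noise, since the smallest chi-square per degree of freedom between libraries of a group was 5.64. That statistic covers counting noise only, so it does not show that the samples are independent. P-values measure the spread between these groups of complexes, in which batches of material are mixed. The batch of each sample is not given in the sources used here, so no value within a batch could be computed.

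The procedure was tested on simulated counts for 12311 genes with 200 changed genes, 50 for each fold size. It recovered 22% of genes changed 1.25-fold, 76% at 1.5-fold, 82% at 2-fold and 96% at 4-fold, and made 6 false calls among 12111 unchanged genes. Of 27 unchanged lists 0 were called. Their members were simulated independently of each other, so this does not test lists whose genes vary together between libraries. Alternatives covered normalisation, the count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, a surrogate variable (sva 3.50.0), covariates, thresholds and left-out libraries. Permutation tests of correlations used 100000 resamples in Python 3.11.15 with numpy 2.4.6.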

Results

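Bovine cumulus-oocyte complexes, each an oocyte within its layer of cumulus granulosa cells, were matured in vitro in groups of 50 with or without polystyrene particles 50 nm in diameter at 3 µg/mL. Polyadenylated RNA was sequenced from 6 control and 6 nanoplastics samples. The design text describes the samples as independent and derived from 3 batches of bovine material, without saying which sample came from which batch. The total count averaged 17464255 ± 1535327 (SD, n = 6) in control and 17094581 ± 2010424 (SD, n = 6) in nanoplastics libraries, with a range over all libraries of 14167578 to 20008464. A gene with at least 1 count was found for 14042 ± 165 gene rows (SD, n = 6) in control and 14038 ± 117 (SD, n = 6) in nanoplastics libraries.

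The main comparison asked which transcripts of the complex differed after maturation with the particles. No gene passed an adjusted p of 0.05. Transcripts of the oocyte growth factors GDF9 and BMP15, of the hyaluronan synthase HAS2 and of the antioxidant enzyme HMOX1 differed between the groups by less than the spread between libraries. The largest log2 fold change among the 18 genes fixed by name was that of HSPA5, the main chaperone of the endoplasmic reticulum, at 982 ± 160 CPM (SD, n = 6) in control and 1858 ± 1345 CPM (SD, n = 6) in nanoplastics libraries, and it did not pass either.

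Among 12311 tested genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 259 genes (2.10% of those tested), of which 132 had a positive and 127 a negative log2 fold change. DESeq2, run without the count filter on 15496 genes, called 0 genes, with 319 (2.06%) at an unadjusted p under 0.05. With limma-voom on the 12311 genes 0 were called, with 232 (1.88%) under that level. The 95% interval of the fold change lay within 1.5-fold in either direction for 10246 genes (83.2%) and within 2-fold for 11749 genes (95.4%). On simulated counts with the same means and library sizes, the test recovered 76% of genes changed 1.5-fold and 82% of genes changed 2-fold, and 22% at the smallest simulated change. The simulation held no variation shared by genes between libraries, and 5.11% of its unchanged genes had an unadjusted p under 0.05, so these shares may not carry over to the real libraries.

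The 10 genes with the smallest p are given as values, since none passed the adjustment. IRF1 (ENSBTAG00000031231), a transcription factor of the interferon system, had a log2 fold change of 0.27 (SE 0.07), at 25.6 ± 1.44 CPM (SD, n = 6) in control and 30.8 ± 2.05 CPM (SD, n = 6) in nanoplastics libraries, and all 6 nanoplastics libraries lay above the control median. PCGF1, a Polycomb group protein, had a log2 fold change of 0.40 (SE 0.11), and GRAMD1A, a cholesterol transfer protein, one of 0.22 (SE 0.07). AJM1 had a log2 fold change of 0.97 (SE 0.30) at a low level of 0.726 ± 0.253 CPM (SD, n = 6) in control libraries. The negative values were −0.26 for EVI5 (SE 0.07), −0.40 for MCEE (SE 0.11), an enzyme of methylmalonyl-CoA metabolism, −0.52 for CCDC149 (SE 0.16) and −0.22 for SIX4 (SE 0.07). TMEM236 had a log2 fold change of −0.67 (SE 0.20) and FRMD7 one of −1.24 (SE 0.35), both below 2 CPM in either group. The adjusted p was 0.999 for each of these genes. For each of the 10, all 6 nanoplastics libraries lay on one side of the control median, a separation that choosing by smallest p favours.

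**Figure D1:**
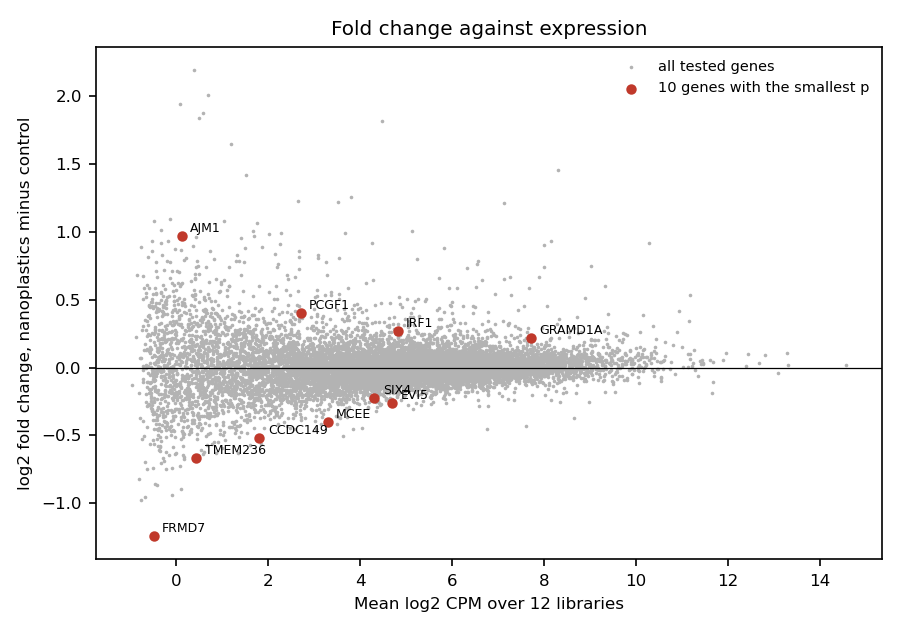
Log2 fold change, nanoplastics minus control, against the mean log2 CPM over 12 libraries, one point per tested gene, with the 10 genes of smallest p in red. None of the 12311 genes passed an adjusted p of 0.05, and the points spread most at low expression.

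Genes of the oocyte and of cumulus function, fixed in advance, gave intervals that included 0. The oocyte factor GDF9 had a log2 fold change of 0.08 (95% interval −0.40 to 0.55) and BMP15 one of −0.23 (−0.56 to 0.10). ZP3, a zona pellucida protein, varied widely between libraries, with a value of 0.44 (−0.88 to 1.76). Of the genes of cumulus expansion, HAS2 had 0.11 (−0.06 to 0.27), TNFAIP6 had 0.15 (−0.06 to 0.37), PTX3 had 0.19 (−0.27 to 0.66) and PTGS2, the inducible prostaglandin synthase, had 0.51 (−0.03 to 1.05). The gap junction protein GJA1 had 0.21 (−0.06 to 0.47), the FSH receptor FSHR 0.22 (−0.14 to 0.58), aromatase CYP19A1 −0.20 (−0.81 to 0.40) and the cholesterol carrier STAR −0.16 (−0.58 to 0.25).

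Genes of stress and cell death were likewise not called. HMOX1 had a log2 fold change of 0.07 (95% interval −0.16 to 0.30), NQO1 one of −0.20 (−0.82 to 0.41) and the autophagy receptor SQSTM1 one of 0.04 (−0.10 to 0.19). BAX, which promotes apoptosis, had −0.03 (−0.25 to 0.20) and BCL2, which opposes it, had −0.02 (−0.25 to 0.21). DDIT3, a transcription factor of the unfolded protein response, had 0.25 (−0.18 to 0.67). HSPA5 had 0.92 (0.24 to 1.60; adjusted p = 0.999), with all 6 nanoplastics libraries above the control median. Nanoplastics 1, 2 and 5 stood at 4119, 1961 and 1758 CPM, above the highest control library at 1212 CPM. Nanoplastics 3, 4 and 6, at 1009, 967 and 975 CPM, lay within the control range of 847 to 1212 CPM. Without Nanoplastics 1 the log2 fold change of HSPA5 was 0.45. Over the 12 libraries HSPA5 had r = 0.82 with the mean log2 CPM of the hypoxia list, a relation looked at after the data were seen. That mean, which also varied among control libraries, was likewise highest in Nanoplastics 1, 2 and 5.

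**Figure D2:**
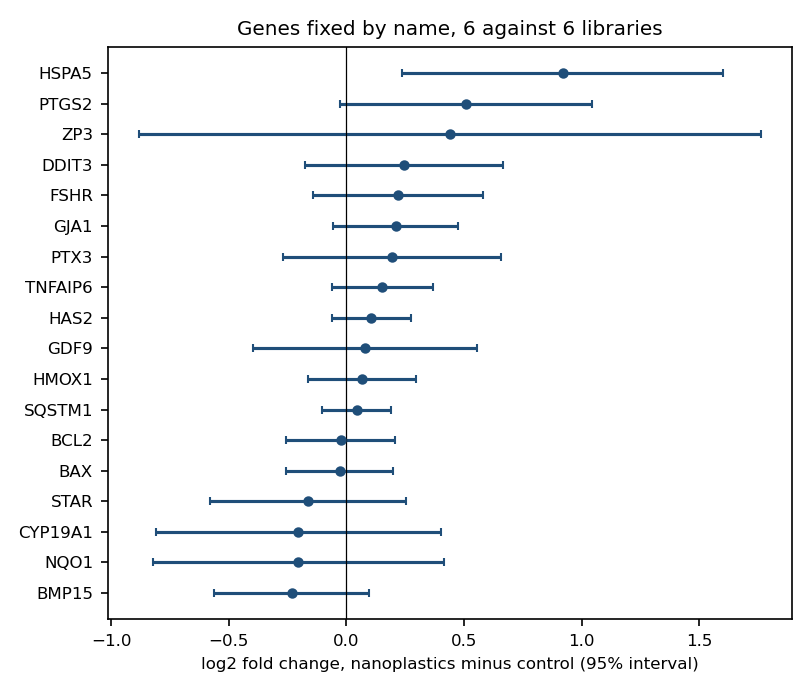
Log2 fold change, nanoplastics minus control, of the 18 genes fixed by name, with points for the estimate and bars for the 95% interval from 6 against 6 libraries. The interval of HSPA5 (0.24 to 1.60) is the only one that excludes 0 before adjustment, and no gene had an adjusted p under 0.05.

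The comparison of gene lists asked whether genes of a common function moved together. Genes of the oxygen and glucose response, of protein folding stress and of cumulus expansion lay mostly above 0, and genes of the interferon response, the cell cycle and the oocyte mostly below. All 22 hypoxia response genes had positive values, with a median log2 fold change of 0.42, as did 23 of 24 glycolysis genes (median 0.24) and 24 of 28 genes of the unfolded protein and integrated stress response (median 0.14). Of the interferon response genes, 29 of 35 had negative values (median −0.09). The sizes lean in part on Nanoplastics 1. That library had the highest mean log2 CPM of all for hypoxia (7.60), glycolysis (8.89) and the unfolded protein list (7.14). It had the lowest for the interferon list (4.88). With camera's preset correlation 12 of 27 tested lists passed an adjusted p of 0.05, 9 toward higher and 3 toward lower values. With a correlation estimated for each list, however, 0 passed (smallest adjusted p = 0.468). In the 12 lists the estimated correlation ran from 0.087 to 0.715, against the preset 0.01. Adjusted p-values with the preset correlation, here and below, are therefore likely too small. The directional fry test passed 0 lists (smallest adjusted p = 0.677) and its mixed test 0 (0.784), and no list member passed over all genes tested.

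Toward higher values, the unfolded protein list had an adjusted p of 2.41e-06 with the preset correlation and adjusted p = 0.468 with an estimated correlation. The corresponding adjusted p-values of glycolysis were 6.44e-06 and 0.507, and its most abundant member GAPDH had a log2 fold change of 0.54 (95% interval −0.15 to 1.22). Those of the hypoxia response were 2.38e-05 and 0.507. HIF1A, the most abundant gene of that list and the oxygen-regulated transcription factor itself, had a value of 0.06 (−0.08 to 0.20). The immediate early response (24 of 29 positive, median 0.15, JUND at 0.12) had 4.02e-05 and 0.507. Without Nanoplastics 1, 5 lists no longer passed even with the preset correlation, namely hypoxia (adjusted p = 0.0621), immediate early (0.0892), cumulus expansion (0.0596), endocytosis (0.0600) and interferon (0.997). Cholesterol synthesis passed in that setting toward lower values (adjusted p = 0.00205), which made 8 lists in all.

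Cumulus expansion had 14 of 15 members positive (median 0.15), with adjusted p = 9.11e-04 with the preset and 0.468 with an estimated correlation, while its most abundant gene VCAN had a log2 fold change of 0.02 (95% interval −0.14 to 0.18). Endocytosis, the list closest to particle uptake, had 27 of 35 members positive with a small median of 0.05, with adjusted p = 0.00552 and 0.468 in the same order, and CLTC, the clathrin heavy chain, had 0.02 (−0.09 to 0.13). Cytoplasmic ribosomal proteins had 59 of 74 members positive, also with a median of 0.05 (adjusted p = 1.53e-04 and 0.596; RPLP0 at 0.13), and did not pass without Control 1 (0.222) or Nanoplastics 6 (0.0546). Reads of ribosomal protein genes can be shared with near-identical copies, so these values are uncertain.

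Toward lower values, the interferon response had an adjusted p of 1.53e-04 with the preset and 0.558 with an estimated correlation, and its most abundant gene IFI27 had a log2 fold change of −0.18 (95% interval −0.41 to 0.05). IRF1 was the only member of any list with an adjusted p under 0.05 when adjusted over the list alone (0.0329), and its value of 0.27 went against the direction of the list. Over all genes tested, 0 members of this list passed. The cell cycle and spindle list had 37 of 51 members negative (median −0.08, adjusted p = 6.66e-04 and 0.507, CCND2 at −0.12), and the oocyte markers 21 of 30 (median −0.11, adjusted p = 0.00869 and 0.558). UCHL1, the most abundant oocyte marker, had a value of 0.03 (−0.11 to 0.18). With the preset correlation, the interferon list did not pass without Control 1 (adjusted p = 0.0998), and without Nanoplastics 1 it pointed toward higher values (0.997). The cell cycle list did not pass without Control 1 (0.0816) or Nanoplastics 5 (0.153), nor the oocyte list without Control 1 (0.322), Control 3 (0.523), Nanoplastics 2 (0.123) or Nanoplastics 5 (0.264), and 7 lists passed in all without Control 1.

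The lists of markers of cells outside the complex were also uneven, though a member need not be confined to such cells. Theca and stromal markers had 10 of 12 members positive (median 0.13, adjusted p = 6.66e-04 with the preset and 0.468 with an estimated correlation), with COL1A1 at 0.09 (95% interval −0.16 to 0.35). COL1A2, named after its values were seen, stood at 15.0 CPM in Nanoplastics 2 and 7.13 CPM in Nanoplastics 6. Every other library held at most 2.20 CPM. COL6A3, likewise named afterwards, had 10.4 and 6.00 CPM in these libraries and at most 2.16 CPM elsewhere. COL3A1 did not set Nanoplastics 6 (6.27 CPM) apart from Nanoplastics 5 (6.82 CPM) or Control 5 (6.05 CPM). COL1A1 did not follow COL1A2, at 1018 ± 230 CPM in control and 1085 ± 73.2 CPM in nanoplastics libraries (SD, n = 6 each). Leukocyte markers had 8 of 10 members positive (median 0.30, adjusted p = 0.0283 and 0.507), with CD68 at 0.06 (−0.37 to 0.49), and did not pass without Control 1 (0.0940), Nanoplastics 5 (0.412) or Nanoplastics 6 (0.0852). With Nanoplastics 2 and 6 both left out, a choice made after seeing the data, theca and stromal markers had an adjusted p of 0.0445 with the preset correlation, and leukocyte markers (0.142) and ribosomal proteins (0.558) did not pass. Extracellular matrix (0.0263), mitochondrially encoded genes (0.0285) and nuclear oxidative phosphorylation (0.00873) passed in that setting, which made 13 lists in all. In that order, these lists also passed without Nanoplastics 6 alone (0.0131, 0.0124 and 0.00199) and without Control 2 (0.0445, 9.66e-04 and 0.00197). Extracellular matrix passed as well without Control 3 (0.0316), and nuclear oxidative phosphorylation without Control 4 (0.0224), Nanoplastics 3 (0.0265) or Nanoplastics 4 (0.0382).

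The other 15 lists did not pass over all 12 libraries with either correlation. Their adjusted p-values with the preset correlation were 0.0897 for extracellular matrix (THBS1 at 0.04) and for nuclear oxidative phosphorylation (ATP5F1A at 0.05), 0.127 for granulosa and cumulus markers (SERPINE2 at 0.03) and for mitochondrially encoded genes (COX1 at −0.04), and 0.142 for lysosome and autophagy (PSAP at 0.12). They were 0.160 for gap junctions and cell adhesion (CTNNB1 at 0.01), 0.190 for inflammation and NF-kB (RELA at 0.15), 0.245 for cholesterol synthesis, and 0.421 for heat shock (HSPB1 at 0.05) and for steroid synthesis and luteinisation (NR5A2 at 0.14). They were 0.676 for apoptosis and p53 targets (MCL1 at 0.06) and for aryl hydrocarbon and xenobiotic response (TIPARP at 0.09), 0.786 for endothelial markers (KDR at −0.02) and for lipid storage and fatty acid use (SCD at −0.11), and 0.90 for antioxidant and NRF2 targets (FTH1 at 0.06). For the antioxidant list the median was positive (0.00451) and the mean negative (−0.00250).

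**Figure D3:**
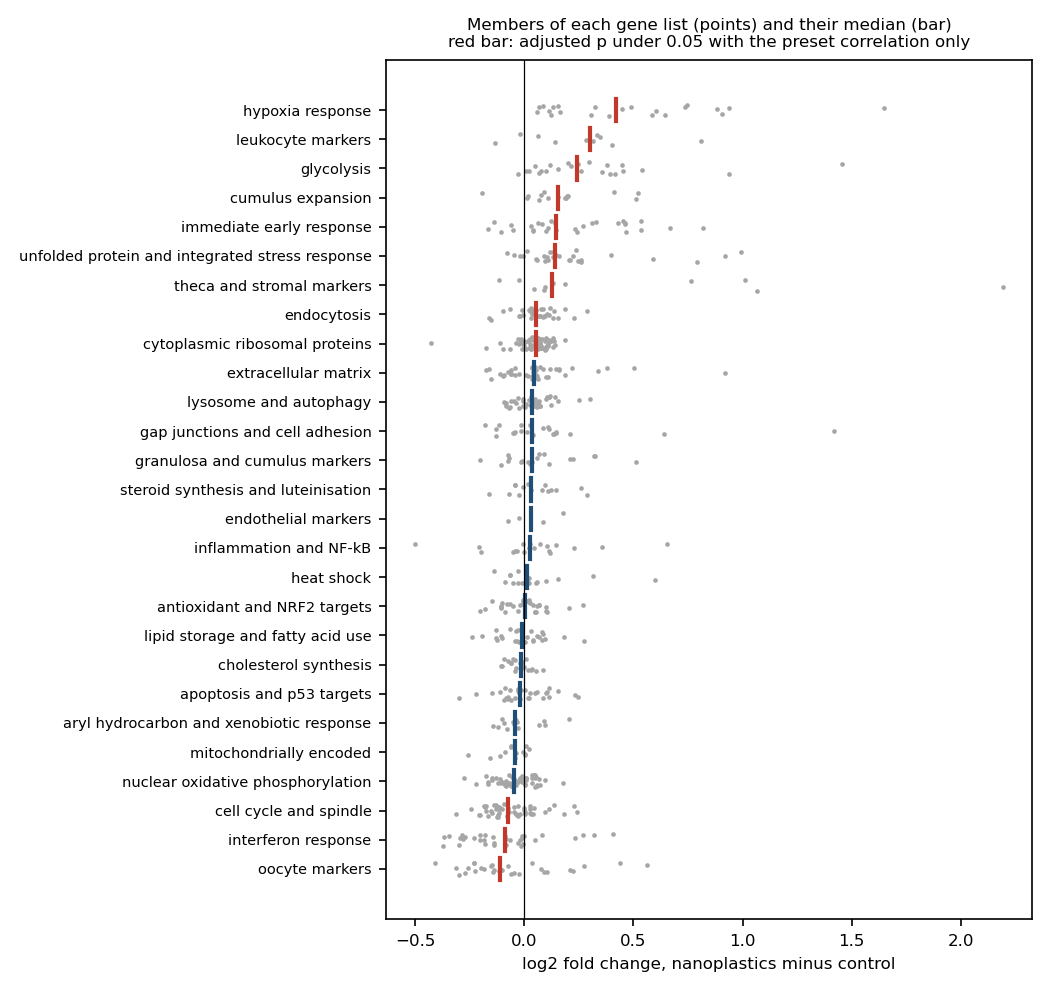
Log2 fold change, nanoplastics minus control, of each tested member (points) of 27 gene lists, with the median of each list as a bar. Red bars mark the 12 lists with an adjusted p under 0.05 with the preset correlation, of which 0 passed with an estimated correlation.

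The comparison of library composition asked whether the mix of oocyte, cumulus and other RNA differed. Oocyte markers took 0.168% ± 0.0185 of counts (SD, n = 6) in control and 0.157% ± 0.0212 (SD, n = 6) in nanoplastics libraries. Mitochondrially encoded genes took 2.15% ± 0.219 and 2.04% ± 0.192 (SD, n = 6 each), ribosomal protein genes 5.51% ± 0.402 and 5.61% ± 0.334, and the 100 most abundant genes 22.9% ± 0.550 and 23.5% ± 0.474. The mean log2 CPM of theca and stromal markers was 3.79 ± 0.10 in control and 4.13 ± 0.34 in nanoplastics libraries (SD, n = 6 each), with p = 0.0455 in a two-sided exact permutation test and 0.519 after adjustment over 12 measures. None of the 12 measures passed the adjustment.

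The remaining measures of composition did not pass either. Granulosa and cumulus markers had a mean log2 CPM of 6.40 ± 0.09 in control and 6.48 ± 0.06 in nanoplastics libraries (SD, n = 6 each; exact permutation p = 0.110, adjusted p = 0.519). Leukocyte markers had 0.46 ± 0.37 and 0.73 ± 0.40 and endothelial markers 2.16 ± 0.26 and 2.23 ± 0.17. Red blood cell markers, of which only HBA and HBM were expressed enough to be tested, had 2.01 ± 1.94 and 2.62 ± 2.93. HBA had a log2 fold change of 1.82 with a wide interval of −0.42 to 4.06, and this list was too short for a list test. Oocyte markers had a mean log2 CPM of 3.60 ± 0.29 and 3.57 ± 0.27.

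The authors' deposited table of the same contrast lists 11416 genes, with one adjusted p of 0.999928 throughout, so that 0 genes pass there. At an unadjusted p under 0.05 the authors' deposited table holds 234 genes. IRF1 also has the smallest p in the authors' deposited table, with a log2 fold change of 0.26, ahead of EVI5 at −0.26 and MCEE at −0.40. Across 11353 genes in both tables, which are not independent replicates, the fold changes of the authors' deposited table and of edgeR had a Spearman correlation of 0.99997. Both tables held 196 genes at an unadjusted p under 0.05 in each, and 0 genes past the threshold in both.

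The libraries also differed within each group in genes of the oxygen response. The mean log2 CPM of the hypoxia list ran from 5.36 to 6.89 in control and from 5.63 to 7.60 in nanoplastics libraries. VEGFA ran from 6.76 to 10.99 on the log2 CPM scale over the 12 libraries, and HBA from 1.09 to 8.43.

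**Figure D4:**
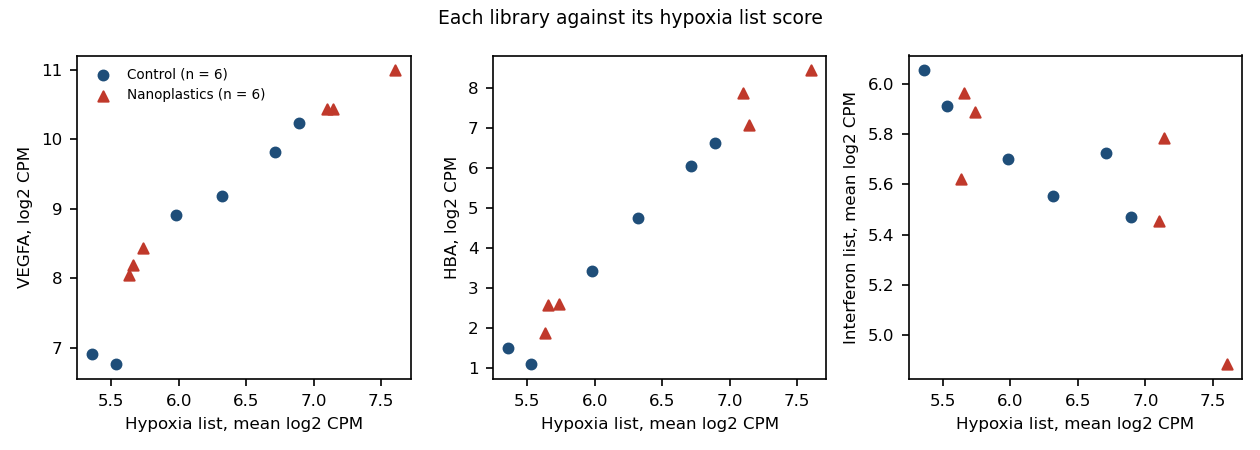
Log2 CPM of VEGFA, log2 CPM of HBA and mean log2 CPM of the interferon list, each against the mean log2 CPM of the hypoxia list, one point per library (6 control, 6 nanoplastics). Libraries of both groups lie along the same trends, with hypoxia values from 5.36 to 6.89 in control and 5.63 to 7.60 in nanoplastics libraries.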

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

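The flagged values here come from a comparison of each library with the others of its group. In it, the gap of the most extreme library to its nearest neighbour was divided by the range of the group. The comparison was run on 136 groups of values and set 5 of them apart (3.68%). Chance alone sets apart about 1 in 20, or 6.8 here.

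Control 5 accounted for 3 of the 5. Its log2 CPM was 11.16 for the small heat shock protein HSPB1 against 11.55 to 11.75 in the other control libraries. It was 6.47 for the NF-kB subunit RELA against 6.74 to 6.85, and 7.95 for the AP-1 subunit JUND against 8.53 to 8.87. Nanoplastics 5 had 9.88 for the collagen gene COL1A1 against 10.08 to 10.15 in the other nanoplastics libraries, and Nanoplastics 6 had 0.60 for TMEM236 against −0.08 to 0.17. These counts of extreme libraries were not above the number chance gives. Outside that comparison, Control 5 stood at 27.9 on the second principal component (13.2% of the variance), the other control libraries at −14.2 to 4.03. Its chi-square per degree of freedom against other control libraries was 26.9 to 43.3, against 9.04 to 29.8 among the rest.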

How the results depend on the processing

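Added after the data were seen were the hypoxia covariate, the deposited log2 values, summed rows of one ID, the pair of Nanoplastics 2 and 6 left out, and the lists under other scalings and 1 surrogate variable. The count of called genes was 0 in the main setting and in all 34 alternatives, with unadjusted counts from 106 to 482 genes. None of the 1757 values of named genes crossed the threshold, and 85 of them, in 22 genes, had the other sign.

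The number of lists was 12 in the main setting, 0 with the estimated correlation, 0 with fry and 3 with 1 surrogate variable, and 7 to 15 when single libraries were left out. Under the surrogate variable, which follows the hypoxia score (r = −0.98), the hypoxia list pointed lower (adjusted p = 0.0273), and the interferon list pointed higher (0.707), as it did without Nanoplastics 1 (0.997, against a lowest adjusted p of 3.93e-08 with another library left out). The surrogate variable is close to the hypoxia list's own score, so the direction of that list under it cannot be read. The cause of the other turns was not tested. The other values were 8 with the hypoxia covariate, 11 with library size only and 12 with RLE size factors. Of 539 list values, 466 stayed on their side of the threshold without a called direction turning, 55 lost the call, 15 gained one and the 3 above turned. Of the 466, 22 pointed the other way and passed in neither setting.

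Samples of one replicate number correlated by over 0.1 in 2 of 6 pairs, and 1 of 6 correlated best with its own number, so the numbers were not taken to pair samples. The replicate block gave 0 genes and 12 lists, with extracellular matrix in place of oocyte markers, and 0 of 12 measures of composition. At the depth and gene-wise spread of these libraries, the smallest simulated change was recovered in 22% of genes.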

Other observations

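The gene test and the list test with the preset correlation were fixed before the data were examined, and the bound for sequencing depth was set before its result was seen. The correlations with the hypoxia score, its use as a covariate, the surrogate variable for lists, and the tests of the oocyte share and of dilution, of the particles as the whole cause, of variation shared by members of a list and of red blood cells were chosen after seeing the data, as were the genes singled out.

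Genes of the oxygen response differed widely between libraries within both groups. VEGFA, the vascular growth factor, spanned 11.1-fold among the 6 control libraries and 7.73-fold among the 6 nanoplastics libraries. The glucose transporter gene SLC2A3 spanned 47.2-fold and 61.0-fold, and BNIP3, a mitophagy receptor, 6.44-fold and 8.68-fold. The first principal component held 33.7% of the variance. The mean log2 CPM of the hypoxia list was 6.13 ± 0.62 (SD, n = 6) in control and 6.48 ± 0.90 (SD, n = 6) in nanoplastics libraries. The difference lay within the spread (exact permutation p = 0.435). Nanoplastics 1, 2 and 5 had 7.60, 7.10 and 7.14, above every control library (at most 6.89). Nanoplastics 3, 4 and 6 had 5.63, 5.66 and 5.73, in the lower part of the control range of 5.36 to 6.89.

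Other gene groups moved with the hypoxia score across the 12 libraries, and 14 of 28 relations had an adjusted permutation p under 0.05 for r and 12 for rho. Glycolysis rose with it (22 genes outside the hypoxia list, r = 0.97, rho = 1.00, both p = 1e-05, the smallest these permutations can give, adjusted p = 9.33e-05, and r = 0.95 without Nanoplastics 1 and 5). The unfolded protein list also rose (r = 0.93, permutation p = 5e-05, rho = 0.90, p = 2.3e-04, adjusted p = 3.36e-04, and r = 0.90 without those libraries). The interferon list ran the other way (r = −0.78, permutation p = 0.00102, rho = −0.73, p = 0.00957, adjusted p = 0.00408 for r and 0.0268 for rho, and r = −0.82 without those libraries). Within control libraries the interferon relation had r = −0.87 (n = 6, exact permutation p = 0.0278) and within nanoplastics libraries r = −0.73 (n = 6, exact permutation p = 0.0750). The permutations exchanged libraries freely across the batches of material, which are unknown per sample. Libraries of a shared batch may be alike, so these p-values, here and below, may be too small.

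The percent of counts in oocyte markers fell as the hypoxia score rose (r = −0.91, permutation p = 1e-04, rho = −0.92, p = 1.1e-04, adjusted p = 3e-04 for r and 3.3e-04 for rho over 3 relations, and r = −0.86 without Nanoplastics 1 and 5). Within control libraries r was −0.84 (n = 6, exact permutation p = 0.0292) and within nanoplastics libraries −0.95 (n = 6, exact permutation p = 0.0278). Of the 30 tested oocyte markers, WEE2 (r = −0.86) and BTG4 (r = −0.88) were among the strongest falls. UCHL1, the most abundant, had r = −0.63. GDF9, at a lower level, had r = 0.21, but CNOT6L, at a level near BTG4 (mean log2 CPM 6.51 and 6.66), had r = 0.11.

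What sets the hypoxia score of a library is open. Sequencing depth explained 0.246% of its variance (at most 5.38% without any 1 library), and the particles cannot be the whole cause, since the SD among control libraries alone was 82.0% of the SD among all 12. The percent of counts in oocyte markers explained 82.3% of the variance (77.3% to 87.7% without any 1 library). The mean log2 CPM of the same list, in which each member counts alike, explained 9.56%. Members at or above the level of ZAR1L (mean log2 CPM 4.58) had r from −0.88 to −0.52 with the score, except CNOT6L (r = 0.11). Members below that level ran from r = −0.71 to r = 0.28. The abundant markers thus fell with the score, apart from CNOT6L. Whether the oocyte share of the RNA sets the score stays open, since a correlation does not give the direction. Dilution by oocyte RNA alone would raise all cumulus transcripts alike, yet granulosa and cumulus markers rose by only 0.0761 log2 (0.0560 to 0.0906 without any 1 library) per log2 unit of the score. Oxygen supply, the number of cumulus cells per oocyte or the batch of material may contribute, and were not tested because the labels give none of them per sample.

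The 12 lists that passed with the preset correlation did not exclude chance. Of 100 splits of the 12 libraries drawn from 462, the real one included, 10 gave at least as many lists, and the highest other split gave 15. Members of these lists varied together between libraries. Among the 12, the estimated correlation ran from 0.087 (theca and stromal markers) to 0.715 (hypoxia response), above the preset 0.01. P-values with the preset correlation are therefore likely too small, and 0 lists passed with the correlation estimated for each list. Shared variation of members is thus a candidate explanation for the 12 lists. With the hypoxia score as a covariate 8 of 26 other lists passed, and with the surrogate variable that follows it 3 of 27. Those 3 were the unfolded protein list, cytoplasmic ribosomal proteins and the hypoxia list itself, which was left out of the first count only. The other splits gave a median of 8 lists without any covariate, so these counts leave open how much of the pattern comes from the hypoxia score. 

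HBA, a hemoglobin alpha gene, followed the hypoxia score closely (r = 0.99, rho = 0.99, both permutation p = 1e-05, adjusted p = 9.33e-05, and r = 0.99 without Nanoplastics 1 and 5). Its counts ran from 36 to 5860 per library. Red blood cells carried over with the complexes would also bring HBB, but 0 counts were found for HBB in all 12 libraries. With up to 3 counts allowed by a count of 0, HBB is limited to 0.0193% of the 15582 HBA counts. This limit holds only if HBB reads could be counted, which the sources used here do not show. The red cell gene SLC4A1 had 0 counts and ALAS2 had 1. HBM, the other red blood cell marker expressed enough to be tested, went the other way with 529 counts (0 to 151 per library). It rose with the hypoxia score too (r = 0.94, permutation p = 6e-05, adjusted p = 3.36e-04). Transcription of HBA within the complex, in step with the oxygen response, is a hypothesis that was not tested further, and reads shared between hemoglobin copies may affect both HBA and HBB.

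For single genes the real count was 0, which all 100 of 100 splits reach by construction, so this count says nothing about chance. Any gene was called in 5 of the other splits, and the highest gave 614. Whether such calls reflect a structure of the libraries other than the treatment was not tested. The 4 splits with over 10 genes parted the libraries by at least 0.72 in mean hypoxia score, against 0.35 in the real split, although 12 splits had so wide a gap. The surrogate variable followed the first principal component (r = −0.999) and the hypoxia score (r = −0.98). At an unadjusted p under 0.05 the real comparison held 259 genes, against a median of 448 in the other splits, of which 21 of 99 held as few.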
